A study of Mus musculus with 12 samples.

How the data were processed

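Poly(A)-enriched RNA of mouse PGCLCs was sequenced, per the labels. The cells came from J1 male embryonic stem cells and were sorted from day 2 or day 6 embryoid bodies for CD61 (Itgb3) and SSEA1. Per the submitters' processing notes, reads were checked with FastQC 0.10.1, trimmed with Trim Galore 0.6.3 and cutadapt (version not stated), aligned to mm10 with STAR 2.7.6a and quantified with Cufflinks 2.2.1.

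The deposited table gives FPKM values by the authors for 12955 genes in 12 libraries. The values carry an added 1, which was inferred from their digits: 90.1% of values between 1.1 and 2 had 7 or more digits, against 0% of values from 2 to 10. That 1 was subtracted. Depth per library is not stated, so FPKM cannot be turned into counts and the precision of low values is unknown; summed FPKM ran from 550230 to 673435 per library. The table held 0 mitochondrial genes, so 13 listed mitochondrial transcripts were not analysed here, and 19 symbols had the form of a date. Positions came from GENCODE M21 by symbol for 12436 genes; 519 did not match.

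Groups followed the labels: 6 groups of 2 libraries. One title spells the compound differently, and its treatment field, which names dTAG13, was used. Genes with FPKM of at least 1 in 2 libraries (12059) were tested with limma 3.58.1 in R 4.3.3, on log2(FPKM + 1), with a trended prior variance. One linear model held all 6 groups (6 residual degrees of freedom; prior degrees of freedom 3.86). An adjusted p (Benjamini-Hochberg) below 0.05 counted as a change. Comparisons were OE against EV at each day, the difference between those effects, dTAG13 against DMSO, day 6 EV against day 2 EV, and DMSO against EV. Group levels are means ± SD of n = 2, and errors of log2 changes are standard errors from the model.

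Of 26 gene lists fixed before the data were seen, 24 had 5 or more tested members and were tested with camera at a preset correlation of 0.01, and again with the correlation estimated. Adjusted p values run over the 24 lists of a comparison. The fibroblast and feeder list had 3 tested members and no test. Members not in the table numbered 17 for posterior and Hox genes, 11 for primitive streak and mesoderm, 10 for endoderm, 9 for neural ectoderm, 9 for endothelial and blood genes, 7 for trophoblast and amnion, 7 for Wnt targets, 5 for cardiac and muscle, 4 for Wnt pathway components, 2 for germ cell specification, 2 for formative and primed, 2 for BMP targets and 1 each for ribosome biogenesis, DNA methylation and hypoxia. Another 3 lists were added after the results were seen. These were adjusted over those 3 lists alone. Each list test was also run with an estimated correlation and without D2_dTAG replicate 1. Shared calls were compared with Fisher's exact test. Chromosome segments were found from running medians over 9 genes with a threshold of 0.4, after the data were seen.

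Named genes followed a rule fixed beforehand: Tex10 and Itgb3; up to 8 genes per direction with the largest change past the threshold (5 for the difference of OE effects and for DMSO against EV); and up to 3 changed members of each list, or 2 as plain values where none passed. The genes taken by size of change had both libraries of a group beyond both of the other and a mean of 5 FPKM or more in the higher group, and unnamed gene models were left out. Fut4, the other sorting marker gene, was absent from the table. Genes named for lying in a segment or on the Y chromosome, those named as shared between comparisons, and the genes listed at 0 were chosen after their values were seen. The analysis was tested on simulated data with 50 changed genes per size. Noise was drawn independently per gene with 1 spread per library and expression level, so rates for the real data, where genes of a level differ, may differ. With the excess spread of the dTAG13 pair in D2_dTAG replicate 1, main fits recovered 8% at a log2 change of 0.5, 42% at 1, 84% at 2 and 92% at 3 for OE at day 2. For dTAG13 they recovered 12%, 40%, 90% and 92%. With that excess in both dTAG13 libraries, recovery at a log2 change of 1 was 24% for OE at day 2 and 52% for dTAG13. False calls were 0 of 113 and 0 of 117 while the excess spread sat in D2_dTAG replicate 1. In the fit without that library they were 25 of 197 (12.7%) and 12 of 166 (7.23%), and with sample quality weights 14 of 182 (7.69%) and 14 of 103 (13.6%). They rose to 801 of 941 (85.1%) for dTAG13 when both dTAG13 libraries had it, and to 5283 of 5457 (96.8%) without D2_dTAG replicate 1. Alternatives covered the pseudocount, the low-value filter, quantile normalization, median-ratio scaling, a replicate block, only the groups compared, no trend, other thresholds, sample quality weights, leaving out each library of the groups compared or D2_dTAG replicate 1, and leaving out segment genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.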

Results

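Tex10, a nuclear protein tied to ribosome maturation and pluripotency, was followed in mouse primordial germ cell-like cells (PGCLCs), cultured counterparts of the embryonic precursors of sperm and eggs. The 12 libraries formed 6 groups of 2: EV and OE at day 2 and at day 6, and DMSO and dTAG13 at day 2. The labels abbreviate EV and OE without spelling them out. dTAG13 is a small molecule that brings suitably tagged proteins to degradation, and DMSO is its solvent. The 2 libraries of a group may not come from separate cultures. All changes are on the log2(FPKM + 1) scale, which understates changes of low genes.

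The Tex10 gene (chromosome 4, 48430858 to 48473459) read 119 and 145 FPKM in day 2 EV and 403 and 378 in day 2 OE. At day 6 it read 65.7 and 81.5 in EV and 259 and 269 in OE. The DMSO libraries read 61.7 and 56.8, and the dTAG13 libraries 45.2 and 36.5. Tex10 rose in OE by 1.57 at day 2 (SE 0.15, adjusted p = 0.0028, n = 2 per group) and by 1.84 at day 6 (SE 0.15, adjusted p = 0.000862). With dTAG13 the Tex10 transcript fell by 0.53 (SE 0.15, adjusted p = 0.0425), or -0.68 without D2_dTAG replicate 1, while the median gene stood at -0.127. That p used the spread shared by all 6 groups, and with only the 2 groups compared no gene passed. A degrader acts on protein, and Tex10 protein was not measured here. Itgb3, which encodes the sorting marker CD61, stood at 0.02 in OE at day 2 (adjusted p = 0.997) and 0.69 at day 6 (adjusted p = 0.247). With dTAG13 Itgb3 stood at -0.56 (adjusted p = 0.214), and at -0.12 without D2_dTAG replicate 1. Itgb3 was low there, at 1.29 and 0.73 FPKM with DMSO. It was listed at 0 in D2_dTAG replicate 1 and read 0.83 in D2_dTAG replicate 2. The cells were also sorted for CD61, which may limit how far its gene could differ.

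**Figure D1:**
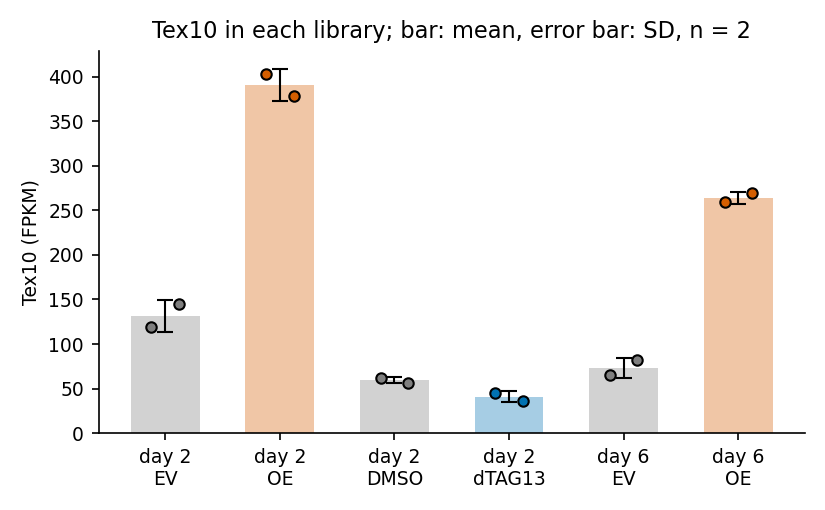
Tex10 expression in each of the 12 libraries (FPKM), by group; n = 2 libraries per group.

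D2_dTAG replicate 1 differed from all other libraries in how many genes were listed at 0: 2008 genes (15.5%), against 18 to 127 elsewhere. Of these, 115 genes averaged above 5 FPKM in the 11 other libraries. The share at 0 was 57.7% among genes averaging below 1 FPKM and 0.140% among those above 20. Fgf17, a growth factor gene, was listed at 0 there, against 8.71 FPKM in the other dTAG13 library and 38.7 and 44.3 with DMSO. Atp8b2 was listed at 0 against 4.61 (DMSO 11.9 and 11.2), Crxos against 5.88 (DMSO 14.2 and 11.1), and Stmn3 against 6.40 (DMSO 11.9 and 14.4).

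**Figure D2:**
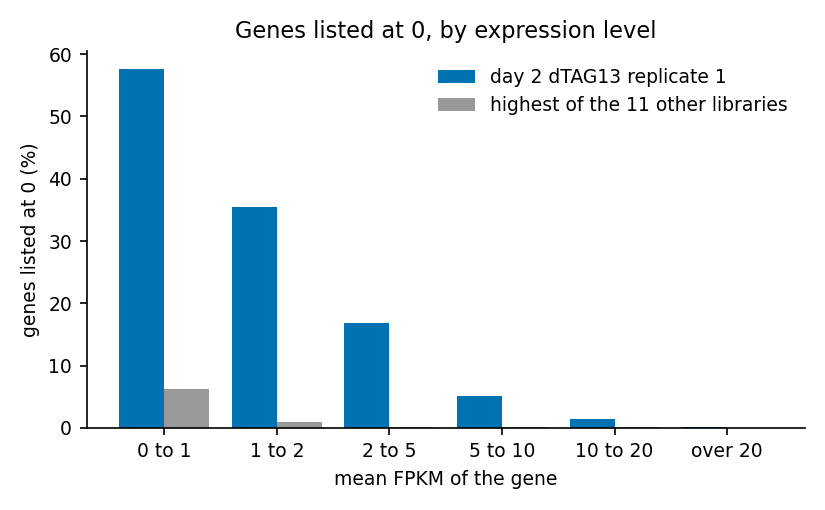
Share of genes listed at 0 in D2_dTAG replicate 1 and the highest share among the other libraries, by mean expression without D2_dTAG replicate 1.

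Neighbouring genes shifted together along parts of 2 chromosomes. On chromosome 8, from 3515384 to 47990924, 123 genes had a median OE difference of -0.54 at day 2 and -0.50 at day 6, against 0.09 for DMSO over EV. Of these, 107 were lower in OE at both days (87.0%, against 27.4% elsewhere). Segments were placed by these same differences, so such shares and medians partly follow from that choice. Genes past the threshold in the segment included the p53 target Ckap2, -0.95 at day 2, and the pluripotency gene Zfp42, -0.83 at day 6. On chromosome 6, from 65042583 to 71285319, 8 genes had medians of 0.89 and 1.02 in OE and 0.85 with DMSO, all against EV. Here the EV libraries stood apart, at -0.63 and -0.46 (day 2) and -0.58 and -0.43 (day 6) from the average of all libraries, while the others lay between 0.08 and 0.65. From 87887814 to 95718800, 28 genes had a median of 0.90 with DMSO over EV and 0.06 and -0.02 in OE. In 1000 shuffles of gene order the number of 9-gene windows past 0.4 never exceeded 33, 75 and 19; the data had 154 (OE, day 2), 221 (OE, day 6) and 39 (DMSO over EV). D2_dTAG replicate 2 over DMSO also had more windows (144) than its shuffles (at most 108), in runs of at most 9 windows on many chromosomes; the chromosome 8 run in OE at day 2 reached 91. These counts cover all chromosomes together and do not test a single segment. The largest window median in OE at day 6, 0.9994, lay below the largest in its shuffles, 1.009. For OE at day 2 it lay above (0.8686 against 0.741), as for DMSO over EV (0.9687 against 0.9548). Shorter runs lay on other chromosomes in OE too, and the median gene of chromosome 6 as a whole stood at 0.135 (day 2) and 0.150 (day 6) in OE.

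**Figure D3:**
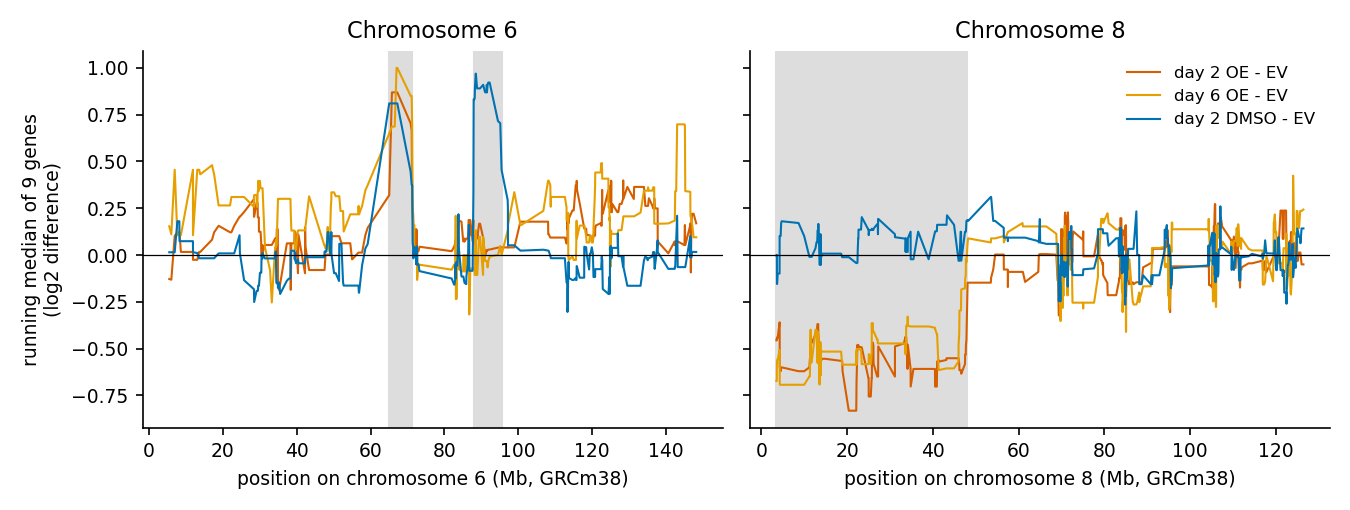
Running median of expression differences along chromosomes 6 and 8 for OE against EV at both days and DMSO against EV.

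At day 2, the genes changed in OE included p53 targets and genes of sugar use, both in lists fixed beforehand. Genes of amino acid use were among them too, but were grouped only after the results were seen. Trib3, a stress-response kinase-like gene, rose by 1.96 (SE 0.16, adjusted p = 0.00179; 31.7 ± 0.346 against 7.40 ± 0.427 FPKM, n = 2). Hk2, which starts glycolysis, rose by 1.49 (SE 0.15, adjusted p = 0.00506), and Aldh18a1, for proline synthesis, by 1.52 (SE 0.25, adjusted p = 0.0292). Nanos3, needed for germ cell survival, fell by 1.59 (SE 0.30, adjusted p = 0.0462; 14.8 ± 5.33 against 45.7 ± 11.2 FPKM). The other largest rises were Rpph1 (2.29, adjusted p = 0.0131), Pla2g1b (2.22, adjusted p = 9.22e-05), Tuba3a (1.68, adjusted p = 0.0116) and Pcolce (1.35, adjusted p = 0.0465). The largest falls were the hormone gene Sct (-2.33, adjusted p = 0.00654), Xlr3b (-2.31), Xlr3a (-2.24), Aldh3b2 (-1.80), Pnma5 (-1.72), Krtdap (-1.71), Snhg14 (-1.68) and the iron exporter gene Slc40a1 (-1.64). Xlr3a was also lower in the DMSO libraries than in these EV libraries, so at day 2 EV stood above both groups for it.

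Of 24 p53 target genes, 5 fell in OE at day 2 and 0 rose (14 fell when adjusted over the list alone; median -0.65). Dcxr (-1.25, adjusted p = 0.0131) and Plk2 (-1.03, adjusted p = 0.0102) were among them. The list as a whole was lower at an adjusted p of 1.26e-11; the adjusted p = 0.116 with an estimated correlation. Of 19 hypoxia and glycolysis genes, 4 rose and 0 fell (9 rose adjusted over the list alone), including Pfkp by 0.93 and Tpi1 by 0.90. That list gave an adjusted p of 4.33e-06, and the adjusted p = 0.359 with an estimated correlation. Tpi1 had an adjusted p of 0.0824 under quantile normalization and 0.0624 under median-ratio scaling. Tpi1 lies on chromosome 6, where the running median around it stood at 0.37.

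Other lists moved at day 2 mostly without single genes past the threshold. Ribosome biogenesis genes (0 of 29 past it) were higher at an adjusted p of 3.61e-05 (adjusted p = 0.411 with an estimated correlation); Nop2, on chromosome 6, stood at 0.46 against 0.39 for the running median around it. Cholesterol synthesis genes (0 of 18; Mvd 0.54) were higher at 0.00102 (adjusted p = 0.411 with an estimated correlation). Cell cycle genes were higher at 0.0049 (adjusted p = 0.652 with an estimated correlation); 1 of 25 rose, Aurka, by 0.56, and 2 adjusted over the list alone. Late germ cell genes (0 of 19, 1 lower adjusted over the list alone; Stk31 -0.88) were lower at 0.0049 (adjusted p = 0.602 with an estimated correlation). Cardiac and muscle genes (0 of 6; Tagln -1.19) were lower at 0.0208 (adjusted p = 0.602 with an estimated correlation) and the Tex10 complex (1 of 13 rose, Tex10 itself) higher at 0.0456 (adjusted p = 0.621 with an estimated correlation; 0.0879 without D2_dTAG replicate 1). Trophoblast and amnion genes gave 0.0577, and 0.00956 (lower) without D2_dTAG replicate 1 (adjusted p = 0.325 with an estimated correlation). The cardiac and muscle, Tex10 complex and cell cycle lists passed no longer under quantile normalization, at 0.0672, 0.292 and 0.0672, or without D2_EV replicate 1, at 0.140, 0.174 and 0.217. Under median-ratio scaling the cardiac and muscle list gave 0.0720 and the Tex10 complex 0.0600. The Tex10 complex list includes Tex10, so part of its shift is that of Tex10 itself, and its other members were not tested alone in any comparison. Its name is a label: it also holds partner and ribosome assembly genes such as Prmt1, Bop1 and Pes1, so it does not stand for a single complex. Among 16 germ cell specification genes only Nanos3 changed (list adjusted p = 0.161). Apoptosis and stress genes included 2 of 19 that rose, Trib3 and Asns (0.73; list adjusted p = 0.551).

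In all, 53 genes were higher and 49 lower in OE at day 2 (52.0% higher; 40% of 190 under median-ratio scaling), and 1483 of 12059 had an unadjusted p under 0.05. The spread between the dTAG13 libraries enters the pooled spread, and without D2_dTAG replicate 1 the count was 1688. Leaving out 1 of the 4 libraries compared gave from 1 gene (without D2_OE replicate 2) to 19 (without D2_EV replicate 1).

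At day 6, 3 of 19 late germ cell genes rose in OE and 4 of 11 formative and primed genes fell; neither list passed with an estimated correlation (adjusted p = 0.899 and 0.202). Dazl, an RNA-binding germ cell gene, rose by 2.18 (SE 0.46, adjusted p = 0.0326; 27.2 ± 6.30 against 5.17 ± 0.501 FPKM, n = 2). Stra8, a meiotic entry gene, rose by 1.46 (SE 0.27, adjusted p = 0.0197), and Dmrt1, a gonadal regulator, by 1.49 (SE 0.34, adjusted p = 0.0414). Id3, a BMP target, fell by 2.43 (SE 0.09, adjusted p = 2.57e-06; 32.9 ± 0.339 against 181 ± 2.64 FPKM). Lefty1, a Nodal antagonist, fell by 1.93 (SE 0.19, adjusted p = 0.0015). Among the largest changes were rises of Tuba3b (2.18), Vegfa (2.00), Cdx1 (1.86) and Zfp516 (1.73), and Serbp1 (2.01) and Gng12 (1.61), inside the chromosome 6 segment in which EV stood apart. The largest falls included Lgals3 (-2.44, adjusted p = 0.000102), Aoah (-2.37), Nkx2-9 (-2.28), Enox1 (-2.09), Alox5ap (-1.81) and Mup6 (-1.78).

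Of 19 late germ cell genes, 3 rose in OE at day 6 and 0 fell (4 rose adjusted over the list alone), at a list adjusted p of 0.00102 (adjusted p = 0.899 with an estimated correlation). Of 16 germ cell specification genes, 3 rose: Dppa3 by 1.24, Kit by 1.08 and Dppa5a by 0.45. The other 13 did not pass, and the list adjusted p was 0.243; adjusted over the list alone, 5 were higher and 3 lower. Dppa5a stood at 0 under quantile normalization. That method gives 0 to any gene with the same rank in every library compared, so this value alone cannot tell whether Dppa5a rose. Under median-ratio scaling Dppa5a stood at 0.37 (adjusted p = 0.125). Dppa3 lies within a run of 12 windows on chromosome 6, from 120836212 to 124415067, with a median of 0.44 in OE at day 6. Of 11 formative and primed genes, 4 fell and 0 rose (4 adjusted over the list alone), including the methylation genes Dnmt3l (-1.74) and Dnmt3b (-0.90). That list gave 0.00047 (adjusted p = 0.202 with an estimated correlation). Of 24 p53 targets, 4 fell and 0 rose (6 lower and 1 higher adjusted over the list alone), among them Plk2 (-1.01), Sesn2 (-0.96) and Btg2 (-0.91). The list adjusted p was 0.00047 (adjusted p = 0.579 with an estimated correlation).

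Single members of other lists also changed in OE at day 6. Aurka rose by 0.43, the only 1 of 25 cell cycle genes, at a list adjusted p of 0.0207 (adjusted p = 0.899 with an estimated correlation; 0.0653 under quantile normalization, 0.105 without D6_EV replicate 1 and 0.171 without D6_OE replicate 1). Naive pluripotency genes went both ways: Tfcp2l1 rose by 0.71 while Nr0b1 fell by 1.25 (2 rose and 2 fell; list adjusted p = 0.97). Among Wnt targets, Cdx1 and Ccnd1 (0.92) rose and Lef1 (-1.63) fell (list adjusted p = 0.97). The Wnt acyltransferase gene Porcn fell by 1.08 (list of Wnt pathway components, adjusted p = 0.97). Cdh1 rose by 0.96 (core pluripotency, adjusted p = 0.97), Vim fell by 1.06 and Gadd45b rose by 1.45. The endoderm (0.432), neural ectoderm (0.48), endothelial and blood (0.821), posterior and Hox (0.787) and primitive streak and mesoderm (0.97) lists did not pass. In all, 232 genes were higher and 216 lower (51.8% higher; 38.8% of 621 under median-ratio scaling), with 2173 at an unadjusted p under 0.05. Leaving out 1 of the 4 libraries compared gave from 18 (without D6_EV replicate 2) to 69 (without D6_EV replicate 1), and leaving out D2_dTAG replicate 1 gave 3044.

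Some genes answered OE differently at the 2 days. Gadd45g, a growth arrest gene, stood at -1.29 at day 2 and 1.21 at day 6 (difference 2.50, SE 0.29, adjusted p = 0.0155). Id3 had a difference of -2.32 (SE 0.13, adjusted p = 0.000117). Trh, a hormone gene inside a chromosome segment, stood at 1.19 and -1.78. In the test of the difference 8 genes were higher and 20 lower at day 6 (1303 at an unadjusted p under 0.05); leaving out 1 of the 8 libraries compared gave 2 to 7, and leaving out D2_dTAG replicate 1 gave 1336 (669 higher and 667 lower). The list tests here are of this same difference, where upward means a higher OE effect at day 6 and downward a lower one. Neither is a change of expression with time. For late germ cell genes the OE effect shifted upward at an adjusted p of 1.72e-07 (adjusted p = 0.466 with an estimated correlation). Of these, 0 of 19 passed the threshold and 4 did when adjusted over the list alone. Germ cell specification genes shifted upward at 0.00377 (adjusted p = 0.718 with an estimated correlation). Cholesterol synthesis genes shifted downward at 0.000627 (adjusted p = 0.488 with an estimated correlation). Formative and primed genes shifted downward at 0.00667 (adjusted p = 0.466 with an estimated correlation; 0.0664 without D2_dTAG replicate 1). Hypoxia and glycolysis genes shifted downward at 0.0302 (adjusted p = 0.718 with an estimated correlation; 0.0892 without D2_dTAG replicate 1, 0.714 without D2_OE replicate 2, 0.132 without D6_EV replicate 1 and 0.0700 under median-ratio scaling). Tex10 itself differed by 0.27 (adjusted p = 0.729).

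With dTAG13, 14 of 24 p53 target genes and 7 of 19 apoptosis and stress genes rose at day 2 (list adjusted p = 0.0589 and 0.134 with an estimated correlation). Mdm2, which restrains p53, rose by 2.31 (SE 0.22, adjusted p = 0.000468; 443 ± 163 against 86.0 ± 10.2 FPKM, n = 2; 1.92 without D2_dTAG replicate 1). Ddit3, a stress transcription factor, rose by 1.83 (SE 0.15, adjusted p = 0.000244; 1.89 without D2_dTAG replicate 1). Lin28a, an RNA-binding germ cell specification gene, fell by 2.05 (SE 0.22, adjusted p = 0.000709; -1.73 without D2_dTAG replicate 1). Ccne1, which drives entry into DNA synthesis, fell by 1.04 (SE 0.13, adjusted p = 0.00214). The largest rises were Rgs14 (3.05), Cpz (2.95), Ms4a10 (2.91), Sct (2.89), Ltb4r2 (2.65), Mst1 (2.63), Cyr61 (2.60) and Fosl1 (2.59). Without D2_dTAG replicate 1 these were 2.95, 2.79, 2.77, 2.97, 3.21, 2.08, 2.18 and 2.28. The largest falls included Fgf17, Msc (-2.95), Calml4 (-2.65), Sulf1 (-2.47), Atp8b2, Stmn3 and Crxos. Fgf17, Atp8b2, Stmn3 and Crxos were listed at 0 in D2_dTAG replicate 1. Without it Fgf17 was -2.13, Msc -1.45, Calml4 -1.64, Sulf1 -1.14, Atp8b2 -1.16, Stmn3 -0.93 and Crxos -0.98. Under median-ratio scaling Sulf1 (adjusted p = 0.0509), Stmn3 (0.0737) and Crxos (0.0654) did not pass.

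Of 24 p53 target genes, 14 rose with dTAG13 and 0 fell (16 higher and 1 lower adjusted over the list alone), with a median of 0.88, or 1.01 relative to all genes. Fas, a death receptor gene, rose by 2.44 (1.66 without D2_dTAG replicate 1) and Rprm by 2.18 (1.42 without it). The list adjusted p was 2.43e-15 (adjusted p = 0.0589 with an estimated correlation), and 1.46e-18 without D2_dTAG replicate 1 (adjusted p = 0.0532 with an estimated correlation). Of 19 apoptosis and stress genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone), including Atf3 (1.95) and Ddit4 (1.36); the list gave 9.76e-05 (adjusted p = 0.134 with an estimated correlation). Of 8 trophoblast and amnion genes, 3 rose, the keratins Krt19 (1.76), Krt18 (1.54) and Krt8 (1.19), at a list value of 0.0101 (adjusted p = 0.355 with an estimated correlation; median 0.43). Without D2_dTAG replicate 1, 5 of the 8 rose at a median of 1.40, and the list gave 3.99e-08 (adjusted p = 0.0426 with an estimated correlation). Of 40 ribosomal protein genes, 3 rose, Rps18 by 0.46, Rps19 by 0.43 and Rpl18 by 0.41 (list 1.41e-06; adjusted p = 0.503 with an estimated correlation; 0.130 under quantile normalization). Under quantile normalization Rps18 stood at 0.13 (adjusted p = 0.388) and Rpl18 at 0.21 (adjusted p = 0.0852).

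**Figure D4:**
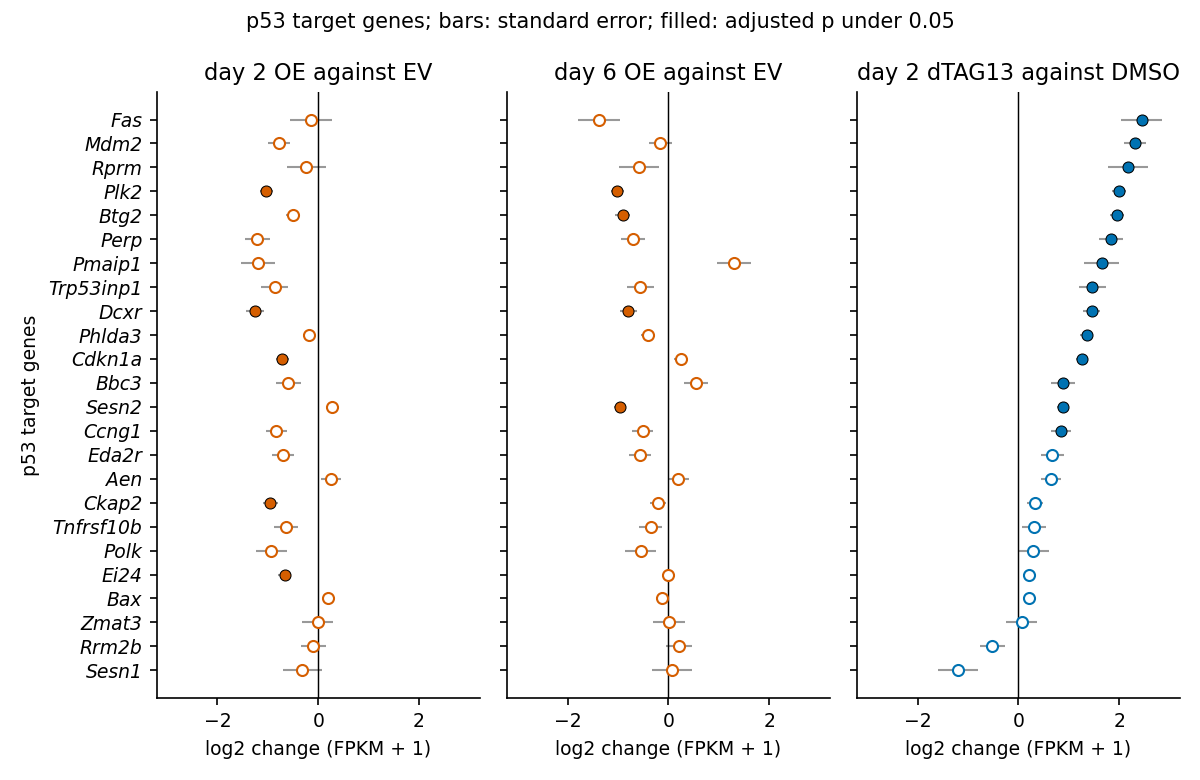
Change of each p53 target gene with dTAG13 and in OE at day 2 and day 6 (log2 scale; n = 2 libraries per group).

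Several lists were lower with dTAG13. Of 18 cholesterol synthesis genes, 7 fell and 0 rose (9 lower adjusted over the list alone); Lss (-0.80) and Msmo1 (-0.79) were among them (list 0.00182; adjusted p = 0.411 with an estimated correlation). Of 11 DNA methylation genes, 4 fell and 0 rose (7 adjusted over the list alone), including the imprint regulator Zfp57 (-1.42), Dnmt3b (-0.74) and Tet1 (-0.74), at 0.0047 (adjusted p = 0.355 with an estimated correlation). Of 16 naive pluripotency genes, 3 fell (5 adjusted over the list alone): Tcl1 (-1.01), Esrrb (-0.89) and Tfcp2l1 (-0.72) (list 0.037; adjusted p = 0.503 with an estimated correlation). Esrrb had an adjusted p of 0.0504 under quantile normalization and -0.55 without D2_dTAG replicate 1. Of 13 genes in the Tex10 complex list, 4 fell (5 adjusted over the list alone): Tex10, Pelp1 (-1.27), Prmt1 (-0.80) and Senp3 (-0.64). That list gave 0.037 (adjusted p = 0.503 with an estimated correlation). Germ cell specification genes went both ways, with 3 higher, among them Dppa3 (0.96), and 4 lower of 16 (list adjusted p = 0.233). Neural ectoderm genes (4 of 6 lower, 0.048; adjusted p = 0.503 with an estimated correlation) and late germ cell genes (3 of 19 higher, Dpep3 2.06, Hormad1 1.39 and Tex101 1.32; 0.00552; adjusted p = 0.503 with an estimated correlation) both gave 0.202 without D2_dTAG replicate 1. The late germ cell median was 0.41 with that library and -0.14 without it, where 3 genes were higher and 2 lower; Dpep3 then stood at 1.62, Hormad1 at 1.05 and Tex101 at 0.79. Pax6 and Map2, of the neural list, were listed at 0 there. Without that library the primitive streak and mesoderm list was higher at 0.00226 (0.233 with it; adjusted p = 0.216 with an estimated correlation). The cell cycle list was then lower at 0.0233 (0.404 with it; adjusted p = 0.671 with an estimated correlation). Without D2_dTAG replicate 2 only the p53 and late germ cell lists passed again; cholesterol synthesis gave 0.261, DNA methylation 0.216, naive pluripotency 0.805, the Tex10 complex 0.760, trophoblast and amnion 0.927, apoptosis and stress 0.0756, ribosomal proteins 0.114 and neural ectoderm 0.114. Without D2_DMSO replicate 2, the Tex10 complex gave 0.0503 and neural ectoderm 0.0714.

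The median gene stood at -0.127 with dTAG13, so a fall of that size does not set a gene apart from the rest. In all, 483 genes were higher and 990 lower (32.8% higher; 53.7% of 1338 under median-ratio scaling), and 3796 had an unadjusted p under 0.05. Without D2_dTAG replicate 1, 750 were higher and 2046 lower, and 1354 of the 1473 passed again in the same direction. The count rests on the spread shared by all 6 groups: with only the 2 groups compared, limma called 0 genes (1258 at an unadjusted p under 0.05), and with sample quality weights 20. Leaving out 1 of the 4 libraries compared gave from 203 (without D2_DMSO replicate 2) to 7223 (without D2_dTAG replicate 2).

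OE at day 2 and dTAG13 shifted some genes in opposite directions. Of 35 genes past both thresholds, 25 moved oppositely: 17 were lower in OE and higher with dTAG13 (1.96 expected, Fisher's exact p = 2.64e-12), among them Sct, Cpz, Ms4a10, Plk2, Dcxr and Cdkn1a. The 8 that were higher in OE and lower with dTAG13 (4.35 expected, Fisher's exact p = 0.0764) included Tex10, Hk2 and Mad2l1. Mad2l1 lies in the chromosome 6 segment in which EV stood apart, and Hk2 with dTAG13 had an adjusted p of 0.116 under quantile normalization. Another 6 were higher in both (2.12 expected, Fisher's exact p = 0.0187), among them Trib3, Cars and Pla2g1b, and 4 lower in both (4.02 expected, Fisher's exact p = 1). Without the segment genes, 17 moved oppositely. Across all genes the correlation was -0.07. Without D2_dTAG replicate 1, 355 of 530 shared genes were opposite, and leaving out 1 other library of these groups gave 0 (without D2_OE replicate 2) to 600 opposite genes (without D2_dTAG replicate 2). The comparisons used no common library, but 1 fit gave each gene the same spread in all of them. A gene with a low spread therefore passes more easily in both comparisons, and genes are not independent replicates. The expected counts and Fisher's exact p values, here and for the OE overlap below, take no account of this. OE at day 2 and day 6 shared 38 genes, 36 in the same direction (15 higher, 1.02 expected, Fisher's exact p = 3.81e-14; 21 lower, 0.878 expected, Fisher's exact p = 1.95e-24). The exceptions were Trh and Gadd45g. The correlation across genes was 0.27. With the segment genes left out, 32 of 33 matched and the correlation was 0.25. Leaving out 1 library of these groups or D2_dTAG replicate 1 gave from 0 (without D2_OE replicate 1) to 546 matching genes (without D2_dTAG replicate 1).

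From day 2 to day 6 in EV, 18 of 19 hypoxia and glycolysis genes rose and 22 of 29 ribosome biogenesis genes fell (list adjusted p = 0.0645 and 0.108 with an estimated correlation). Day and culture batch cannot be told apart in this comparison. Ndufa4l2, a hypoxia-induced mitochondrial gene, rose by 6.06 (SE 0.69, adjusted p = 0.000428; 93.1 ± 0.998 against 0.414 ± 0.0928 FPKM, n = 2). Bnip3, a mitophagy gene, rose by 4.18 (SE 0.51, adjusted p = 0.000602), and the lactate exporter gene Slc16a3 by 4.49 (SE 0.50, adjusted p = 0.000369). Gpx2, an antioxidant enzyme gene, fell by 3.61 (SE 0.23, adjusted p = 2.75e-05). Tex10 fell by 0.83 (SE 0.15, adjusted p = 0.00339). Other large rises were A2m (4.79), Bhlhe40 (4.33), H2-Ab1 (4.32), Copz2 (4.18) and Crtac1 (4.13); large falls were Plac8 (-3.38), Aldh3b2 (-3.22), Spink1 (-3.19), Myl9 (-3.05), Bnipl (-2.86), Fgfbp1 (-2.83) and Lad1 (-2.82). Bnipl had an adjusted p of 0.0556 under median-ratio scaling.

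Of 19 hypoxia and glycolysis genes, 18 rose by day 6 (18 adjusted over the list alone), Adm by 4.01 among them (list 2.88e-17; adjusted p = 0.0645 with an estimated correlation). Of 29 ribosome biogenesis genes, 22 fell (26 adjusted over the list alone), including Nhp2 (-1.18), Gar1 (-1.04) and Ddx21 (-0.98) (list 1.48e-13; adjusted p = 0.108 with an estimated correlation). Of 40 ribosomal protein genes, 10 fell, such as Rpl30 (-0.56), and 6 of 13 genes in the Tex10 complex list fell, such as Wdr18 (-0.74). Those lists gave 3.3e-05 (adjusted p = 0.644 with an estimated correlation; 0.201 under quantile normalization) and 0.000287 (adjusted p = 0.336 with an estimated correlation). Of 6 posterior and Hox genes, 4 rose, Hoxa10 by 1.65 and Hoxb7 by 1.37 (list 0.00205; adjusted p = 0.108 with an estimated correlation). Of 16 germ cell specification genes, 7 fell and 1 rose, including Nanos3 (-2.42) and Rhox9 (-2.04) (list 0.0292; adjusted p = 0.644 with an estimated correlation; 0.219 under quantile normalization and 0.0787 without D6_EV replicate 2). Core pluripotency genes went both ways: Utf1 fell by 1.32 and Tdgf1 rose by 1.53 (1 higher and 4 lower of 10; list 0.0197; adjusted p = 0.372 with an estimated correlation). Dnmt3b fell by 1.63 with 4 of 11 DNA methylation genes lower (list 0.0167; adjusted p = 0.336 with an estimated correlation). The core pluripotency and DNA methylation lists gave 0.201 and 0.201 under quantile normalization. Stra8 rose by 2.68, within a late germ cell list at 0.155. In all, 1600 genes were higher and 1263 lower (55.9% higher; 62.4% of 3177 under median-ratio scaling, 47.8% under quantile normalization and 39.4% among genes with a mean FPKM of 5 or more). Leaving out 1 of the 4 libraries compared gave from 1089 (without D6_EV replicate 1) to 1506 (without D6_EV replicate 2), and leaving out D2_dTAG replicate 1 gave 6267.

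DMSO and EV at day 2 were compared to see how alike the controls were. This is not a treatment comparison. Solvent and any difference of line or culture cannot be told apart here, so no difference below can be credited to DMSO. Tex10 was lower with DMSO by 1.13 (SE 0.15, adjusted p = 0.0104). Txnip, a redox regulator, was higher by 1.75 (adjusted p = 0.000907). The imprinted gene Mest was lower by 4.95 (0.815 ± 0.249 against 55.1 ± 4.94 FPKM, adjusted p = 0.000403, n = 2). The X-linked gene Xlr3a was lower by 3.31. Gata2 (1.66), Suclg2 (1.44), Trh (1.41) and Zxdc (1.36) were higher, all inside the chromosome 6 segments, which held 14 of the 47 genes past the threshold. The Y-linked genes Eif2s3y (39.0 and 42.7 FPKM in EV) and Uty (4.85 and 9.40) were listed at 0 in both DMSO libraries and both dTAG13 libraries. Ddx3y read 10.4 and 18.2 in EV and 0.00347 and 0.00452 with DMSO. Of the lists, BMP targets were higher at 0.00552 (adjusted p = 0.204 with an estimated correlation), with 1 of 10 past the threshold. Trophoblast and amnion genes were higher at 0.0121 (adjusted p = 0.339 with an estimated correlation) and formative and primed genes lower at 0.0183 (adjusted p = 0.339 with an estimated correlation; 0.116 without D2_EV replicate 1). The p53 list was lower at 0.0385 with 0 of 24 past the threshold (adjusted p = 0.768 with an estimated correlation; 0.074 without D2_dTAG replicate 1, 0.197 without D2_EV replicate 2 and 0.175 without D2_DMSO replicate 2). Cell cycle genes were higher at 0.0121 (adjusted p = 0.768 with an estimated correlation; 0.180 without D2_EV replicate 1). Neural ectoderm genes were lower at 0.0183 (adjusted p = 0.442 with an estimated correlation; 0.0651 without D2_DMSO replicate 1), as were ribosomal protein genes at 0.0207 (adjusted p = 0.779 with an estimated correlation; 0.933 without D2_EV replicate 1) and the Tex10 complex at 0.03 (adjusted p = 0.768 with an estimated correlation; 0.117 without D2_EV replicate 2). In all, 30 genes were higher and 17 lower, and 1076 had an unadjusted p under 0.05. Without the segment genes 15 were higher and 16 lower. Leaving out 1 of the 4 libraries compared gave from 1 higher and 8 lower (without D2_DMSO replicate 1) to 2 higher and 13 lower (without D2_EV replicate 1), and leaving out D2_dTAG replicate 1 gave 645 higher and 327 lower.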

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

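Of the tests in this part, both tests of the genes at 0, all 3 segment tests, the p53 test without D2_dTAG replicate 1 and the p53 test in OE were chosen after the results were seen.

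In a direct test of the difference, the OE effect at day 6 differed from the OE effect at day 2 for 28 genes; the 5 named genes with the largest difference each way are given. Higher at day 6 were Gadd45g (2.50, adjusted p = 0.0155), Gstm3 (2.03, adjusted p = 0.0479), Gadd45b (2.00, adjusted p = 0.0165), Tuba3b (1.92, adjusted p = 0.0476) and Krtdap (1.71, adjusted p = 0.0339). Lower were Trh (-2.96, adjusted p = 0.00149), Rpph1 (-2.89, adjusted p = 0.0469), Aoah (-2.51, adjusted p = 0.0248), Enox1 (-2.43, adjusted p = 0.0314) and Id3 (-2.32, adjusted p = 0.000117). When 1 of the 8 libraries compared was left out, 2 to 4 of the 10 still passed. Trh lies in the chromosome 6 segment from 87887814 to 95718800.

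D2_dTAG replicate 1 listed 2008 genes at 0, far more than any other library. Treatment with dTAG13 does not account for it, since D2_dTAG replicate 2 listed 84 genes at 0, against 67 and 66 with DMSO. Fewer molecules sampled in that library cannot be judged. Genes averaging 0.5 to 2 FPKM in the other day 2 libraries, those at 0 included, had a mean above that level by a log2 ratio of 0.35 (-0.14 to 0.17 in the other day 2 libraries), but the smallest values above 0 were smaller than elsewhere (1st percentile 0.00992 FPKM against 0.0658 or more). No read counts were used, so the source stays open.

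Genes on chromosome 8 from 3515384 to 47990924 were lower in OE. GC content and gene length do not explain it: the median stayed at -0.52 at day 6 after both were fitted. Fewer gene copies in the OE line could. Of the 123 genes placed from day 2 alone, 89.4% were lower at day 6, and DMSO over EV stood at 0.09. Elsewhere the share was 50% by construction, since differences were centred on the median of those genes. Another lasting difference of the OE line would give the same pattern, so gene copies were not singled out. Regulation by the Tex10 level could not be told apart, since the segment stood at 0.0145 after dTAG13 (bounds -0.04 to 0.13) and the labels do not separate OE from the line that carries it. Those bounds came from resampling the genes of the segment, so they leave out the spread between libraries. DNA was not analysed here.

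Of 24 p53 targets, 14 rose with dTAG13, and 5 (day 2) and 4 (day 6) fell in OE; the list passed in none of these with an estimated correlation (adjusted p = 0.0589, 0.116 and 0.579). D2_dTAG replicate 1 alone does not account for the rise, because without it the median was 0.99 relative to all genes. Cells of another type (trophoblast and amnion) cannot be judged: 4 markers other than keratins had a median of -0.0908, from 0.45 (Gata3) to -0.89 (Gcm1), while without D2_dTAG replicate 1 the whole list had 5 of 8 higher at a median of 1.40 (adjusted p = 3.99e-08). A response to the Tex10 level cannot be judged either. Of the 14 targets that rose, 13 were lower in OE at day 2, as were 8 of the 10 that did not rise (1-sided Fisher's exact p = 0.371). So few targets were not lower that no split could have brought this p under 0.05, so it decides nothing. A line difference in OE and an effect of the compound itself were not tested and stay open.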

How the results depend on the processing

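No gene past the threshold was called in the opposite direction under any alternative, and no list reversed. Counts moved far more, and the cause was not tested except where stated. The numbers of genes changed (main 102 for OE at day 2, 448 for OE at day 6, 1473 for dTAG13, 2863 for day 6 over day 2, 28 for the difference of OE effects and 47 for DMSO over EV) were, in that order where they moved: with only the groups compared 1032, 3429, 0 (1258 at an unadjusted p under 0.05), 5395, 1172 and 197, since the spread then came from those groups alone; with sample quality weights (chosen after seeing the data) 1020, 3897, 20, 5581, 1275 and 583; with an absolute log2 change of 1 or more added 48, 177, 656, 1094 and, for DMSO over EV, 30; with an adjusted p under 0.1 220, 821, 2605, 115 for the difference and 71 for DMSO over EV. Quantile normalization gave 188, 1048, 151 for the difference and 81 for DMSO over EV; median-ratio scaling gave 190 for OE at day 2 and 57 for the difference; no trend gave 55 and 7. Without chromosome-segment genes (chosen after seeing the data) DMSO over EV gave 31.

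With a replicate block the counts were 2, 90, 649, 4 for the difference and 10 for DMSO over EV, the opposite effects of dTAG13 and OE fell to 0 genes (main 25) and the overlap of OE effects to 1 (main 36). Replicate numbers need not pair cultures: residuals of same-numbered libraries correlated at 0.188 (EV and OE, day 2), -0.151 (DMSO and dTAG13), -0.115 (EV and OE, day 6), 0.384 (EV, both days), 0.185 (OE, both days) and -0.047 (EV and DMSO); over all 15 pairs of groups they ran from -0.180 to 0.384, with 0.212 for the unrelated DMSO and day 6 OE. The block costs degrees of freedom, so a lost call there is not a smaller effect.

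Leaving out each library of the groups compared, or D2_dTAG replicate 1 (chosen after seeing the data where it was not compared), gave 1 to 1688, 18 to 3044, 203 to 7223, 1089 to 6267, 2 to 1336 and 9 to 972 genes; the lone library left in a group was assumed to vary like the other groups. Opposite effects then ran from 0 to 600 and the overlap of OE effects from 0 to 546. Under quantile normalization these were 44 and 91, and under median-ratio scaling 48 and 75. Gene list tests (main 8, 4, 10, 8, 5 and 8 of 24) gave 0 for every comparison with an estimated inter-gene correlation in camera (2, 2, 3, 3, 2 and 3 lists at an unadjusted p under 0.05), and 5 to 11, 3 to 4, 2 to 10, 7 to 10, 3 to 7 and 5 to 6 without 1 library. Under quantile normalization 5 lists passed for day 6 over day 2 (4 of the 8 main lists kept, 4 lost) and 5 for DMSO over EV (3 of 8 lost). With log2(FPKM + 0.1), 2 of 8 main lists were lost for OE at day 2, 1 of 10 for dTAG13 and 1 of 8 for DMSO over EV. Without chromosome-segment genes, 1 of 5 was lost for the difference of OE effects. Itgb3 in OE at day 2 (main 0.02, adjusted p = 0.997) was -0.0150 under median-ratio scaling, -0.0164 without D2_EV replicate 1 and -0.0892 without D2_OE replicate 1, and ran from -0.0892 to 0.128 when 1 library was left out. Of 24 named genes past the threshold in OE at day 2, 23 stayed under quantile normalization, 18 with log2(FPKM + 0.1), 2 with a replicate block, and 1 to 11 without 1 of the 4 libraries compared. Count-based tools were not run, as no counts were used here, and depth limits what low genes can show.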

Other observations

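Of the tests in this part, those of the amino acid genes were set after the results were seen, as were 3 gene lists. The third of these lists, of meiotic and piRNA pathway genes, is therefore no independent test of the germ cell genes at either day. The Y-linked test was set before its result.

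Genes that charge transfer RNAs or make serine, glycine and proline were among those that rose in OE at day 2, and lists of them were drawn up for that reason, so no list test is given for day 2. Of 20 cytosolic tRNA synthetase genes, 5 rose, including Nars (0.99), Aars (0.97) and Cars (0.81). Of 12 serine, glycine and proline genes, 3 rose: Aldh18a1, Psat1 (0.95) and Shmt2 (0.92). At day 6, 0 of the 20 and 1 of the 12 rose (list adjusted p = 0.0385 and 0.0343 over the 3 added lists; adjusted p = 0.494 and 0.234 with an estimated correlation; 0.0628 and 0.0195 without D2_dTAG replicate 1). The third added list, of meiotic and piRNA pathway genes, gave 0.0385 at day 6 (higher; adjusted p = 0.234 with an estimated correlation) and 0.103 at day 2 (0.034, lower, without D2_dTAG replicate 1; adjusted p = 0.25 with an estimated correlation).

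Whether OE had a lasting effect on these amino acid genes cannot be judged: all 32 members had a median log2 change of 0.18 in OE at day 6 (bounds 0.07 to 0.34), with 24 higher. Bounds here came from resampling the 32 genes, which may move together, and leave out the spread between libraries. No test of the difference from the day 2 effect is given, since the genes were chosen at day 2. A response to the Tex10 level cannot be judged either, since Tex10 protein was not measured. With dTAG13 the median of the 32 was -0.0074 relative to all genes (bounds -0.09 to 0.09), and 16 were lower. As a set they showed no fall with dTAG13 in these libraries.

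Y-linked genes near 0 in the DMSO and dTAG13 libraries were not explained by fewer reads there, since 4260 other genes in the same EV range had a median DMSO over EV difference of 0.0319. Of the 4 Y-linked genes with 1 FPKM or more in EV, the highest value in those 4 libraries was 0.00992, while the labels give 1 male line. Loss of the Y chromosome or another line could give that; DNA was not analysed here, and the value of 0.0319 only speaks against depth.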
